A study of Mus musculus with 48 samples.

How the data were processed

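The labels list 48 samples: bulk RNA-seq and ATAC-seq of sorted thymic iNKT cells, single-cell RNA-seq of total thymic iNKT cells from 2 mice aged 8 weeks, and bulk RNA-seq of donor conventional CD4 and CD8 T cells before and 7 days after transplantation. Groups came from the labels alone. Nothing in the labels says that bulk replicates came from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical. Titles of each donor T cell group name 2 experiments, JL041 and JL042, with most of its libraries from JL041. Its spread can therefore also hold a difference between experiments, which no fit here separates. iNKT1 RNA libraries sorted as CD4-positive or CD4-negative were not analysed here, and neither was a supplied list of FVB sequence names. Every column used was matched to a group (0 table columns were left unmatched), but the columns of donor T cells carry numbers and no experiment labels, and 3 of them, for CD8 day 0, share a single column name. Those 3 are numbered here in column order.

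Per the labels' protocols, iNKT RNA libraries were made with the TruSeq stranded mRNA kit, donor T cell libraries with SMARTer v4 cDNA and Nextera XT, and single-cell libraries with the Chromium 3′ v2 kit; the RNA libraries were read on a HiSeq sequencer as 75 bp pairs. The deposited values are raw counts, whole numbers per gene (RNA), per region (ATAC) or, as UMI counts, per gene and barcode (single cell). The submitters' processing notes list Cell Ranger 2.1, Seurat 3, STAR 2.5.4, DESeq2 1.22.2, bedtools 2.27.1, HOMER 4.9.1, FastQC 0.11.7, SAMtools, MultiQC, Bowtie2, MACS2 and kallisto, with builds mm10 and GRCm38, and do not say which tool made which table. Whether counting used the strand, and how reads shared by near-identical genes were handled, is not stated, so values of the granzyme, Klra and haemoglobin families carry that uncertainty. Everything below was computed from the deposited counts.

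Gene tables held 52636 gene IDs for iNKT cells (99.6% with a symbol) and 35661 for donor T cells (98.2%). Library totals ran from 26811373 to 33688697 (iNKT RNA), 25323879 to 37055182 (CD4) and 26134241 to 33658426 (CD8), with 11333 to 14166, 17052 to 19890 and 17253 to 19805 genes detected, and from 13299586 to 42964216 over ATAC regions. edgeR's common biological coefficient of variation was 1.29 for iNKT RNA, 0.298 for ATAC, 0.288 for CD4 and 0.195 for CD8.

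Counts were tested with edgeR 4.0.16 (R 4.3.3): low-count filter by group, TMM scaling (CPM values use the same factors), robust quasi-likelihood fit and Benjamini-Hochberg adjustment, with calls at an adjusted p under 0.05. Fits held 6 iNKT RNA, 6 ATAC, 15 CD4 or 15 CD8 libraries, with 1 term per group, and all 30 donor T cell libraries for the difference between the CD8 and CD4 effects. The SE of a fold change was computed from the F statistic. The design written beforehand had 10 iNKT RNA libraries and an experiment term for donor T cells. The fit used 6 because the CD4-positive and CD4-negative libraries were not used here, and the experiment term was not fitted because the columns name no experiment and their order was not used to assign one; no covariate took its place. A fold against a group without counts was bounded with a floor of 3 counts over the group.

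Named genes followed a rule fixed beforehand: per comparison the 6 genes rising most and the 6 falling most (4 and 4 for comparisons between treatments, ATAC and the difference between CD8 and CD4 effects) among those called with a mean log2 CPM of at least 4 and no overlap between the replicates of the groups, leaving out predicted genes, pseudogenes, ribosomal, mitochondrial, immunoglobulin and T cell receptor segment genes, Xist and Y-linked genes; up to 4 members with the smallest p per gene list; and key genes in every comparison (Cd4, Cd8a, Cd8b1, Zbtb16, Tbx21, Gata3, Foxp3, Mki67, Ifng, Il4, Il17a, Gzmb). Some genes that this rule picks are not reported here. Other names, such as further regions at a gene, were chosen after their values were seen. The 27 lists were the type 1, type 2 and type 17 programs, cytotoxicity, NK receptors, iNKT identity and TCR segments, chemokine receptors and homing, naive and quiescence, cell cycle, inhibitory receptors and exhaustion, costimulation and activation, TCR immediate early response, regulatory T cells, follicular helper, interferon response, glycolysis, oxidative phosphorylation, cholesterol synthesis, unfolded protein response, chromatin and lineage transcription factors, and markers of B and plasma cells, myeloid cells, erythroid cells and platelets, thymocytes, gamma delta T cells, lineage co-receptors, and stromal and epithelial cells. Lists with at least 5 tested members were tested with camera (limma 3.58.1) on log CPM (prior count 2) with a preset correlation of 0.01, and again with an estimated correlation and with fry. Comparisons, tests, lists and the settings listed below as set beforehand were chosen before the data were examined.

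ATAC regions keep the coordinates of the deposited table on mm10, whose base is not stated. A region was assigned to the nearest protein-coding gene of GRCm38.p6 within 10000 bp (43252 regions, 79.3%), and lay proximal to it when within 1000 bp of either end of the gene. Regions over 10000 bp were left without a gene but kept in the main fit. All 35 of them cross a power of 10 in their coordinates, so they may not be true regions of open chromatin. For genes called by RNA, the sign of the RNA change was set against the mean change of the gene's called regions, with Fisher's exact test. Same-numbered ATAC libraries deviated together from their group means, with correlations across regions of 0.655 (iNKT1 and iNKT2), 0.525 (iNKT2 and iNKT17) and 0.502 (iNKT1 and iNKT17). They were taken as paired from these values, not from the labels. With 2 libraries per group this evidence is thin, and the counts of calls with a replicate block had been seen when this was decided. The main ATAC fit held no block. ATAC fold changes, SE, adjusted p-values, list tests and the RNA and ATAC comparison below therefore ignore the pairing, except where a block is named. Donor T cell columns share numbers 1 to 3. In 4 of the 13 comparisons of numbered donor groups, all 3 same-numbered pairs deviated together (r over 0.1): CD4 day 7 untreated against day 0 (r 0.252 to 0.438), CD4 iNKT17 against untreated (0.209 to 0.57), CD8 iNKT2 against untreated (0.202 to 0.477) and CD8 iNKT17 against iNKT1 (0.181 to 0.505). These 4 were taken as paired from these values, not from the labels, after block counts from the fits of all CD4 or all day 7 CD8 libraries had been seen. The JL041 titles read I and III for iNKT17 but I and II for the other day 7 groups. A shared column number need not mark a shared title. A batch shared by number would be expected in every group, the other 9 comparisons lack it, and choosing comparisons by this correlation favours calls with a block, so the blocked counts carry that doubt.

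Single cells were called as barcodes with at least 0.1 of the 99th percentile of UMIs among the top 3000 barcodes (765.5 UMIs in thymus A and 801 in thymus B, of 737280 barcodes each), giving 145 and 146 cells; no cell had under 200 genes, and 7 and 1 with over 10% mitochondrial UMIs were removed, leaving 138 and 145. They were analysed with scanpy 1.11.5 and leidenalg 0.10.2 in Python 3.11.15: 2000 variable genes, 30 principal components, 15 neighbors, Leiden resolution 0.8. A cluster took the name of the marker class with the highest mean log2 ratio of CPM inside to outside the cluster (20 CPM added), if that exceeded 0.5, at least 3 of its markers were detected in 10% of cells, and no other class had more markers among the top 10 genes; a cluster of low UMI counts with none of its markers there took no name. Scrublet predicted 7 and 11 doublets, and none was removed. Intervals are exact 95% binomial intervals (scipy 1.17.1) and cover counting error only.

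Overlaps between treatments were set against 20 simulations of unchanged groups sharing the untreated libraries. Calls were recounted for all 10 splits of 3 against 3 libraries, and for 25 splits for each difference between CD8 and CD4 effects. Settings set beforehand for the recounts were DESeq2 1.42.0, RLE size factors, no low-count filter, only the compared groups or day 7 libraries, a replicate block, leaving out each library, total peak counts for ATAC, and other cell thresholds, resolutions and principal components. In groups of 2, leaving out 1 leaves a lone library assumed to vary like the other groups. The number of detected genes as a covariate, CD4 day 0 library 3 left out of the shared fit, column numbers as a replicate block for donor T cells (in the shared fit, with only the compared groups, and with detected genes as a covariate), ATAC without regions over 10 kb, and Leiden resolution 0.4 for bulk against clusters were chosen after seeing the data. The procedure was also tested on simulated data with real counts as the base: changes of 1, 2 and 3 log2 units were called in 0%, 22.4% and 48.5% of genes for iNKT RNA, 5.97%, 85.1% and 97.0% of ATAC regions, 53.7%, 94.0% and 100% of genes for CD4 and 89.6%, 100% and 100% for CD8 libraries. The changes were placed in 200 genes or regions, all with a mean log2 CPM of at least 4, in a single simulated draw per comparison. The rates therefore do not cover genes or regions with fewer counts. Of the unchanged genes or regions, 10, 37, 6 and 6 were also called. Changes of the 3 sizes gave 0, 15 and 32 true calls for iNKT RNA and 4, 57 and 64 for ATAC. They gave 36, 63 and 66 for CD4 and 60, 67 and 66 for CD8. In these single draws of iNKT RNA and ATAC, false calls thus made up more of all calls than the adjusted p threshold allows. In CD4 and CD8 they did not.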

Results

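Invariant natural killer T (iNKT) cells are T lymphocytes that carry a nearly invariant T cell receptor for glycolipids presented by CD1d, and they mature in the thymus into the sublineages iNKT1, iNKT2 and iNKT17. RNA and open chromatin (ATAC-seq, which sequences DNA fragments released from accessible chromatin by a transposase) were measured in sorted thymic iNKT1, iNKT2 and iNKT17 cells of FVB mice, with 2 libraries per sublineage and assay. Total thymic iNKT cells from 2 mice, called thymus A and thymus B here, were profiled as single cells. The remaining libraries came from donor conventional CD4 and CD8 T cells, taken before transplantation (day 0) or 7 days after transfer of FVB cells into major-mismatched BALB/c hosts, with no iNKT cells given (untreated) or with iNKT1, iNKT2 or iNKT17 cells given. Each of these 5 groups held 3 CD4 and 3 CD8 libraries.

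Total gene counts of the iNKT RNA libraries were 31025394 and 33688697 for iNKT1, 28942084 and 27087674 for iNKT2, and 30847526 and 26811373 for iNKT17. Counts over 54524 ATAC regions totalled 42964216 and 25502839 for iNKT1, 17373112 and 13299586 for iNKT2, and 18371274 and 34813023 for iNKT17. The 15 CD4 libraries held 25323879 to 37055182 counts each and the 15 CD8 libraries 26134241 to 33658426. The single-cell libraries held 1123650 unique molecular identifiers (UMIs) in thymus A and 1178177 in thymus B. Below, levels are mean library-scaled counts (CPM) ± SD over libraries, log2 fold changes carry their SE, and adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named.

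The first comparison asked which transcripts separate thymic iNKT2 from iNKT1 cells. Ifng, which encodes interferon-γ, measured 458 ± 146 CPM in iNKT1 and 15.3 ± 14.99 CPM in iNKT2 cells (n = 2 each; log2 fold change −4.90 ± 0.85, adjusted p = 0.0396). Gzmb, the cytotoxic protease granzyme B, measured 404 ± 106 against 0.174 ± 0.0412 CPM, and Il2rb, the receptor chain shared by IL-2 and IL-15, 1523 ± 235 against 147 ± 14.3 CPM. In the other direction, the costimulatory receptor Icos rose from 104 ± 12.1 to 1219 ± 282 CPM (log2 fold change 3.55 ± 0.24, adjusted p = 0.00013), Zbtb16, which encodes the iNKT transcription factor PLZF, from 71.4 ± 34.9 to 631 ± 154 CPM, and the co-receptor Cd4 from 48.7 ± 5.22 to 502 ± 25.1 CPM. Il17rb, a subunit of the IL-25 receptor, had no count in iNKT1 libraries and was at least 3106-fold higher in iNKT2 libraries, against a floor of 3 counts over the group.

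Of 17 tested type 1 program genes, 10 fell in iNKT2 relative to iNKT1 cells, 0 rose and 7 did not pass (14 fell when adjusted over the list alone). The chemokine Xcl1 (278 ± 74.4 against 0.158 CPM), Ly6c2 (555 ± 38.1 against 0.249 CPM) and the IL-12 receptor chain Il12rb2 (151 ± 45.4 against 0.0532 CPM) were among them. Tbx21, which encodes the type 1 transcription factor T-bet, measured 306 ± 1.69 against 10.0 ± 13.7 CPM and did not pass (adjusted p = 0.501). Among 14 cytotoxicity genes 4 fell and 10 did not pass (8 fell when adjusted over the list alone), with Nkg7 at 979 ± 29.2 against 2.47 CPM. Among 10 NK receptor genes 3 fell and 7 did not pass (8 fell when adjusted over the list alone), with the signalling chain Fcer1g at 212 against 0.0543 CPM. The set tests of these 3 lists each gave adjusted p = 0.0552 with an estimated correlation. Camera with the preset correlation gave 4.8e-23, 1.78e-10 and 4.85e-14, and fry gave 0.000595 each. Of 15 type 2 program genes, 5 rose, 0 fell and 10 did not pass (6 rose and 2 fell when adjusted over the list alone; adjusted p = 0.111 with an estimated correlation), including the IL-6 receptor Il6ra (285 ± 73.3 against 0.128 CPM) and the chemokine receptor Ccr4 (148 ± 69.3 against 0.0599 CPM). Il4 at 42.5 ± 7.60 against 0.015 CPM did not pass (adjusted p = 0.207), and Gata3, a type 2 transcription factor, measured 153 CPM in iNKT2 and 175 CPM in iNKT1 libraries. Of 15 naive and quiescence genes 3 rose and 2 fell (5 and 5 when adjusted over the list alone): the transcription factor genes Tcf7 and Lef1 rose (log2 fold changes 1.21 ± 0.22 and 3.36 ± 0.63), while Klf2 fell (−3.44 ± 0.65). The activation marker Cd69 fell from 357 to 7.28 CPM, and 2 of 15 immediate early genes fell (7 when adjusted over the list alone), Junb among them (log2 fold change −1.67 ± 0.26). None of 29 cell cycle, 24 interferon response, 16 glycolysis or 23 oxidative phosphorylation genes passed.

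In all, 159 of 12372 tested genes passed in iNKT2 against iNKT1 cells, 66 higher and 93 lower in iNKT2. DESeq2 called 1177 genes, and the edgeR count was 445 with no low-count filter. Leaving out iNKT1 library 1 gave 315 calls. The spread between same-group libraries was wide (biological coefficient of variation 1.29), with Spearman correlations between replicate libraries of 0.863 for iNKT1, 0.86 for iNKT2 and 0.769 for iNKT17.

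Thymic iNKT17 cells were then set against iNKT1 cells. The IL-1 receptor Il1r1 measured 1113 ± 49.9 CPM in iNKT17 and 0.301 ± 0.13 CPM in iNKT1 cells (n = 2 each; log2 fold change 11.84 ± 0.46, adjusted p = 5.57e-06), and the IL-23 receptor Il23r 585 ± 67.2 against 0.112 ± 0.0734 CPM. Ifng stood at 0.219 ± 0.128 CPM in iNKT17 libraries, Cd4 at 0.207 ± 0.201 CPM and Gzmb at 0.191 ± 0.224 CPM, each below iNKT1. Zbtb16 and Icos rose to 567 ± 31.9 and 1397 ± 48.5 CPM, and Il17rb was at least 2234-fold higher than in iNKT1 libraries, where it had no count.

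Of 17 type 17 program genes, 8 rose in iNKT17 over iNKT1 cells, 0 fell and 9 did not pass (12 rose when adjusted over the list alone). The surface proteoglycan Sdc1 (646 ± 41.9 against 0.14 CPM) and the kinase Blk (2396 ± 879 against 0.668 CPM) rose. Il17a, the cytokine that names the sublineage, measured 27.5 ± 17.5 CPM in iNKT17 and had no count in iNKT1, yet did not pass (adjusted p = 0.398). Of 17 type 1 program genes 11 fell and 6 did not pass (15 fell when adjusted over the list alone), of 14 cytotoxicity genes 6 fell and 8 did not pass (7 fell when adjusted over the list alone), and of 10 NK receptor genes 4 fell and 6 did not pass (7 fell when adjusted over the list alone). The set tests of these 4 lists each gave adjusted p = 0.0635 with an estimated correlation. Camera with the preset correlation gave 7.64e-21, 2.23e-17, 4.04e-07 and 6.46e-08, and fry gave 0.000868, 0.000483, 0.000483 and 0.000483. Il2rb fell to 294 ± 18.5 CPM, and the NK receptor Klra1 from 338 to 0.165 CPM. Tbx21, at 0.165 CPM in iNKT17 libraries, did not pass (adjusted p = 0.105). Of 15 type 2 program genes 4 rose, 1 fell and 10 did not pass (6 rose and 1 fell when adjusted over the list alone; adjusted p = 0.146 with an estimated correlation). Among 15 chromatin and lineage transcription factor genes 3 rose and 12 did not pass (4 rose when adjusted over the list alone), including Id3 (19.0 to 137 ± 27.0 CPM) and Sox13 (24.9 to 573 ± 6.42 CPM). In total 247 genes passed, 122 higher and 125 lower in iNKT17. DESeq2 called 1820 and the unfiltered edgeR test 559. Leaving out 1 library raised the count to 1040 without iNKT17 library 1, 467 without iNKT17 library 2 and 398 without iNKT1 library 1.

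Thymic iNKT17 cells were also set against iNKT2 cells. Il1r1 and Il23r measured 0.331 ± 0.0584 and 0.174 ± 0.0412 CPM in iNKT2 libraries, and rose by log2 fold changes of 11.69 and 11.68 in iNKT17 (adjusted p = 6.01e-06 and 2.25e-05, n = 2 each). Cd4 was lower in iNKT17 by a log2 fold change of −11.27 ± 0.74 (adjusted p = 0.000133). The chemokine receptor Cxcr3 measured 41.5 ± 7.66 CPM in iNKT2 and 0.0776 CPM in iNKT17 (adjusted p = 0.0104), while Cxcr6 rose from 212 to 854 CPM (log2 fold change 2.01 ± 0.23). Zbtb16 and Gata3 did not pass (log2 fold changes −0.15 ± 0.35 and 0.37 ± 0.40). Of 17 type 17 program genes 6 rose and 11 did not pass (10 rose when adjusted over the list alone; adjusted p = 0.137 with an estimated correlation), and of 17 type 1 program genes 3 fell, with Ifng among them, and 14 did not pass (3 rose and 5 fell when adjusted over the list alone). No member of the cytotoxicity list passed. None of 24 interferon response genes passed (3 fell when adjusted over the list alone, adjusted p = 0.137 with an estimated correlation). For the type 17 list (upward) and this list (downward), preset camera gave adjusted p = 3.62e-19 and 1.24e-05, and fry 0.00466 each. The test called 88 genes, 54 higher and 34 lower in iNKT17, where DESeq2 called 1472 and the unfiltered test 339. With only the compared groups in the fit, 43 were called. The count was 157 without iNKT2 library 1, 164 without iNKT2 library 2, 831 without iNKT17 library 1 and 263 without iNKT17 library 2.

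**Figure D1:**
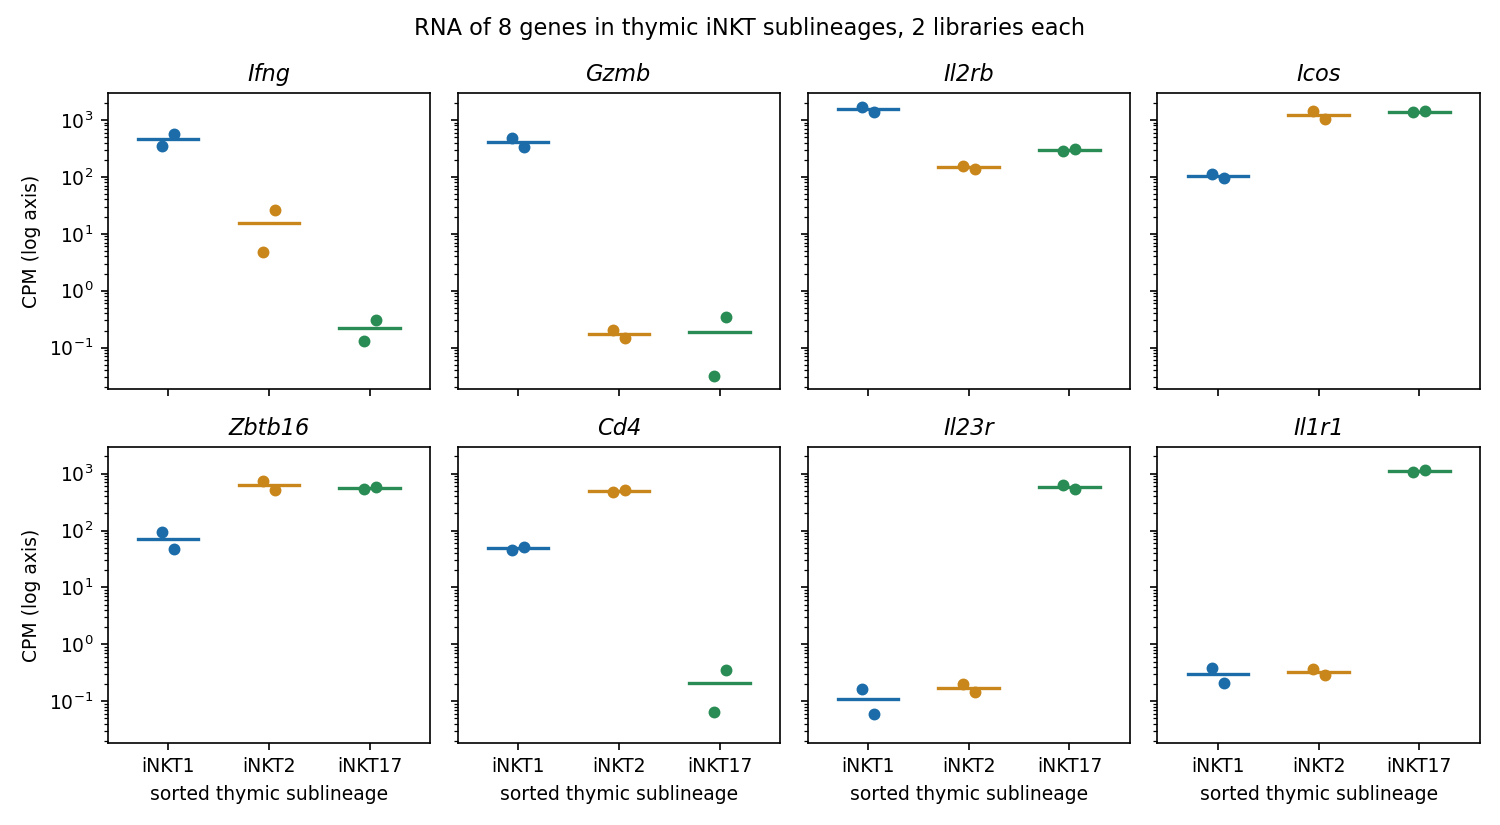
CPM of 8 genes (log axis) in thymic iNKT1, iNKT2 and iNKT17 RNA libraries, with 1 point per library, 2 libraries per sublineage and a line at the mean. Ifng and Gzmb were highest in iNKT1, Cd4 in iNKT2, and Il23r and Il1r1 in iNKT17 libraries.

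Chromatin accessibility was compared between the same sublineages, on mm10 coordinates and in a fit without a replicate block. At the Ifng locus all 3 regions lost signal in iNKT2 and in iNKT17 relative to iNKT1 cells. The region at chromosome 10, 118440595 to 118441249, measured 51.4, 7.71 and 1.19 CPM in iNKT1, iNKT2 and iNKT17 (log2 fold change −2.73 ± 0.29 for iNKT2 and −5.44 ± 0.34 for iNKT17 against iNKT1). Of 9 regions assigned to Tbx21, 6 were lower in iNKT2 and 7 in iNKT17, with 15.6, 1.01 and 0.347 CPM at chromosome 11, 97109037 to 97109374. All 3 Il17a regions were higher in iNKT2 than in iNKT1 and higher again in iNKT17: chromosome 1, 20740257 to 20740938, measured 1.42, 16.99 and 52.7 CPM, and chromosome 1, 20730571 to 20731369, 0.558, 1.97 and 38.8 CPM.

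Zbtb16 carried 34 regions, of which 16 gained and 1 lost signal in iNKT2 against iNKT1, and 13 gained and 1 lost in iNKT17 against iNKT1. The Zbtb16 region at chromosome 9, 48681090 to 48681475, measured 0.529, 15.1 and 3.85 CPM and was also lower in iNKT17 than in iNKT2 (log2 fold change −1.97 ± 0.29). Il23r had 6 regions: 1 rose and 1 fell in iNKT2 against iNKT1, and 4 rose and 0 fell in iNKT17 against either, with 1.05, 1.38 and 24.1 CPM at chromosome 6, 67475449 to 67476250. Both Xcl1 regions and all 3 Ccl5 regions, genes for chemokines of type 1 cells, lost signal in iNKT2 and iNKT17. Xcl1 measured 53.3, 4.18 and 1.26 CPM at chromosome 1, 164935203 to 164936362. Of 14 regions at Gata3, 4 were lower in iNKT2 and 7 in iNKT17 than in iNKT1, and 0 were higher.

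**Figure D2:**
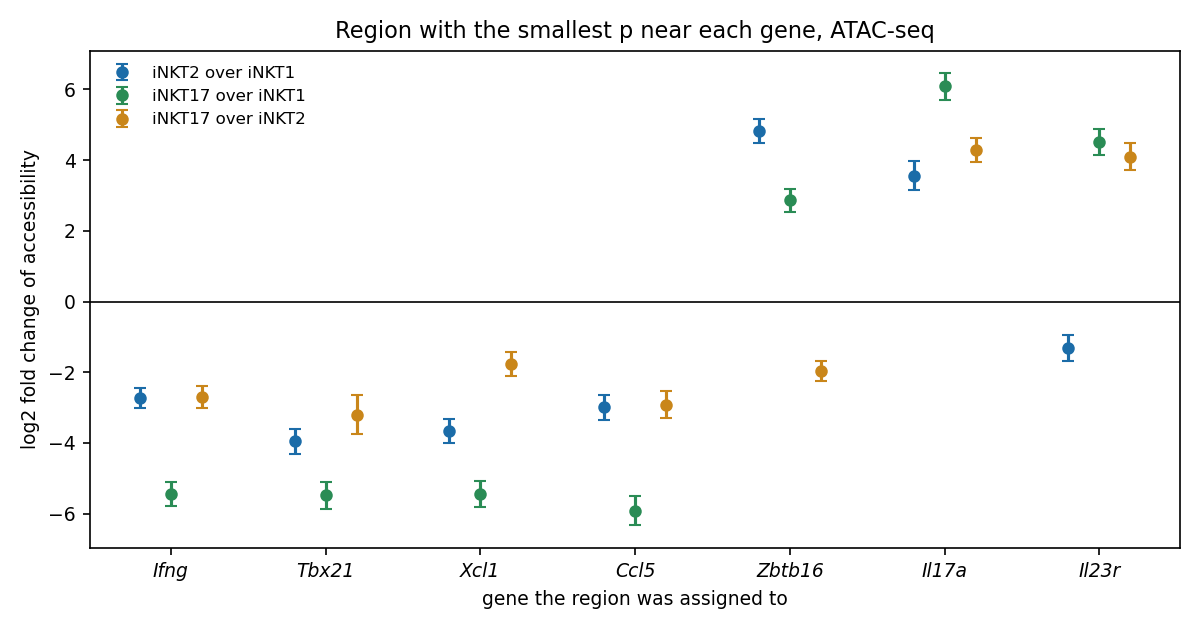
Log2 fold change ± SE of the ATAC region with the smallest p near each of 7 genes, for the 3 comparisons between sublineages (2 libraries each). The region plotted can differ between comparisons. Regions at Ifng, Tbx21, Xcl1 and Ccl5 lay below 0 against iNKT1, and those at Il17a above 0.

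Over all regions, 12138 were more and 8912 less accessible in iNKT2 than in iNKT1, 21050 of 54520 tested (26492 at an unadjusted p under 0.05). Among those that moved most was a region in Dhx32 (chromosome 7, 133734211 to 133734867), at 29.2 ± 6.20 CPM in iNKT2 and 0.331 ± 0.22 CPM in iNKT1 (log2 fold change 6.34 ± 0.45, adjusted p = 0.000168). One in Stat4, which encodes a signal transducer of IL-12 (chromosome 1, 52034672 to 52035716), measured 1.62 against 53.8 CPM (log2 fold change −5.05 ± 0.26). In iNKT17 against iNKT1, 20220 regions passed, 12802 higher and 7418 lower. A Cc2d2a region at chromosome 5, 43728232 to 43729261, rose (log2 fold change 6.64 ± 0.47, 58.5 against 0.563 CPM), and a Mctp2 region at chromosome 7, 72275080 to 72275981, fell (−6.33 ± 0.48, 0.727 against 55.1 CPM). In iNKT17 against iNKT2, 4549 passed, 2785 higher and 1764 lower. A Tmem132d region at chromosome 5, 127784508 to 127785543, measured 83.6 against 2.80 CPM, and one at Il12rb2, chromosome 6, 67347951 to 67348426, 0.902 against 14.6 CPM (log2 fold change −4.02 ± 0.42, adjusted p = 0.00182). With the replicate number as a block, 10102 regions passed in iNKT17 against iNKT2. Without iNKT1 library 2, 11572 regions passed in iNKT2 against iNKT1 and 12884 in iNKT17 against iNKT1. In iNKT17 against iNKT2, 1572 passed without iNKT17 library 2 and 1619 without iNKT2 library 2.

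By gene list, 53 of 78 regions at type 1 program genes fell and 4 rose in iNKT2 against iNKT1, 51 fell and 4 rose in iNKT17 against iNKT1, and 10 fell and 5 rose in iNKT17 against iNKT2. Of 104 regions at type 17 program genes, 46, 68 and 45 rose and 11, 4 and 2 fell in these comparisons. Of 37 regions at NK receptor genes, 22 fell in iNKT2 and 23 in iNKT17 against iNKT1 and 0 rose. Of 90 type 2 program regions, 27 rose and 23 fell in iNKT2 against iNKT1, so this list held no single direction. Of 43 regions at iNKT identity genes, 21 rose and 1 fell in iNKT2 and 16 rose and 1 fell in iNKT17 against iNKT1. Of 148 regions at naive and quiescence genes, 26 rose and 46 fell in iNKT2 against iNKT1. Camera with the preset correlation called type 1 regions downward in iNKT2 and iNKT17 against iNKT1 (adjusted p = 3.25e-14 and 3.93e-16). Fry gave 0.00622 and 0.0029 there. The preset test did not call the type 2 list in iNKT2 against iNKT1 (0.748). With an estimated correlation no ATAC list kept an adjusted p under 0.05. In the order above, it was 0.268, 0.224 and 0.929 for type 1, 0.678, 0.336 and 0.929 for type 17, 0.346 and 0.336 for NK receptors, 0.914 for type 2, 0.441 and 0.611 for iNKT identity and 0.678 for naive genes. Regions at the same gene are not independent.

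RNA and ATAC changes were compared at genes called by RNA that had an assigned called region. The directions matched for 115 of 131 genes (87.8%) in iNKT2 against iNKT1, for 203 of 218 (93.1%) in iNKT17 against iNKT1 and for 49 of 52 (94.2%) in iNKT17 against iNKT2 (Fisher's exact test, 2-sided, p = 2.26e-18, 6.5e-43 and 3.84e-10). Spearman correlations across these genes, which are not independent replicates, were 0.822, 0.871 and 0.851. Over all 9714 genes tested in RNA that carried regions, 55.02%, 58.2% and 54.9% matched in direction.

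In single cells, 138 cells of thymus A (median 5310 UMIs and 1450 genes) and 145 of thymus B (median 5815 UMIs and 1541 genes) were kept. Of 4 clusters, an iNKT1-like cluster led by Ccl5, Fcer1g and Gzma held 54 cells of thymus A, 39.1% (exact 95% binomial interval 30.9% to 47.8%), and 35 of thymus B, 24.1% (17.4% to 31.9%). An iNKT17-like cluster led by Blk, Pxdc1 and Sdc1 held 16 and 30 cells, 11.6% (6.77% to 18.1%) and 20.7% (14.4% to 28.2%). A cluster with 41 and 31 cells, 29.7% and 21.4%, was named interferon-responding T-like; Izumo1r, a type 2 program gene, led it, ahead of Ifit3 and Isg15. A cluster of 27 and 49 cells, 19.6% and 33.8%, was led by Igfbp4, Phgdh and Slc29a1; its best class was iNKT2-like, but its mean log2 marker ratio of 0.374 was under the 0.5 needed for a name. No cluster was named iNKT2-like. At a Leiden resolution of 0.4, 3 clusters were found, and the one of 147 cells, led by Izumo1r, Plac8, Cd4 and Il4, was named iNKT2-like and held 49.3% and 54.5% of cells. The rule that turned marker ratios into names was set once the files could be read and before its outcome was known. With 2 mice, no test between them was made, and the intervals cover counting error only.

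**Figure D3:**
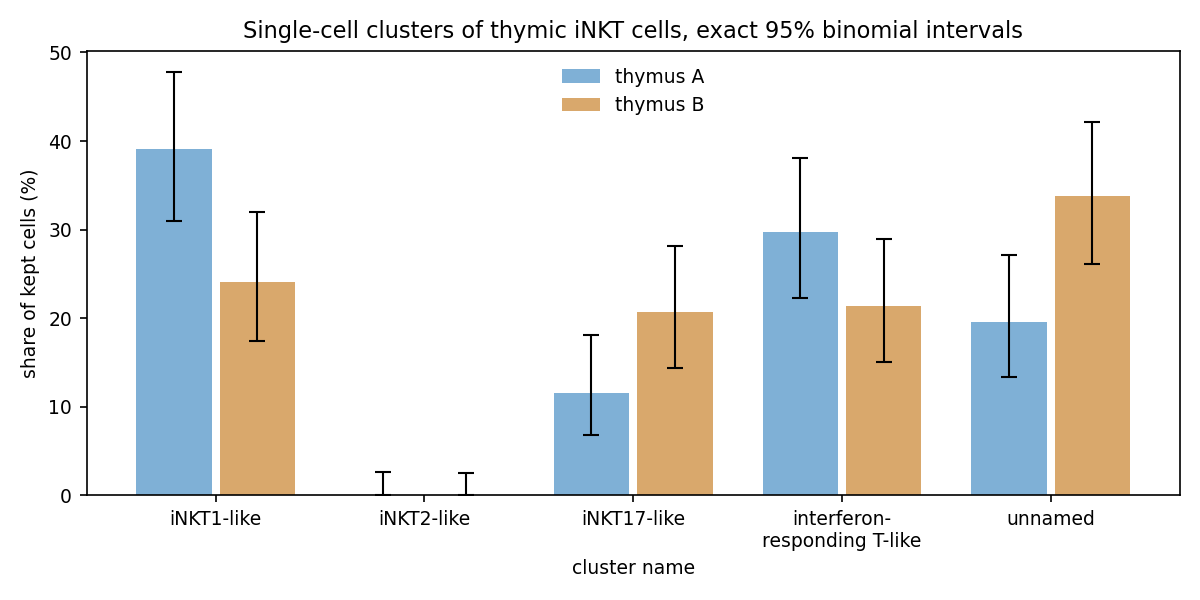
Share of kept cells (%) in each cluster for thymus A (138 cells) and thymus B (145 cells), with exact 95% binomial intervals, at Leiden resolution 0.8. The iNKT1-like share was 39.1% in thymus A and 24.1% in thymus B, and no cluster was named iNKT2-like.

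The bulk fold changes of called genes were set against the difference between the iNKT17-like and iNKT1-like clusters. Across 197 genes in thymus A and 201 in thymus B, Spearman correlations were 0.773 and 0.782, with 94.4% and 95.02% of genes in the same direction. Over all genes tested in bulk the correlations were 0.26 and 0.267. With the clusters found at resolution 0.4, a setting chosen after seeing the data, iNKT2 against iNKT1 gave 0.763 and 0.793, and iNKT17 against iNKT2 gave 0.765 (70 genes) and 0.683 (72 genes).

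Donor CD4 T cells of untreated hosts at day 7 were compared with CD4 cells at day 0. They had gained effector, proliferation and inhibitory receptor transcripts and lost those of naive cells. Gzmb rose from 2.56 ± 1.47 to 629 ± 87.5 CPM (n = 3 each; log2 fold change 7.95 ± 0.56, adjusted p = 2.08e-07), Tbx21 from 29.6 ± 2.21 to 416 ± 44.2 CPM (3.81 ± 0.18) and Ifng from 4.78 ± 1.89 to 46.9 ± 3.54 CPM (3.29 ± 0.34). The proliferation marker Mki67 rose from 5.41 to 79.0 ± 26.2 CPM and the inhibitory receptor Pdcd1 from 20.9 to 552 ± 132 CPM. Ccr7, which directs naive T cells into lymph nodes, fell from 1341 ± 266 to 147 ± 16.2 CPM. The B cell gene Cd79a fell from 135 ± 4.64 to 0.548 CPM and the haemoglobin gene Hba-a1 from 2586 ± 1575 to 1.48 CPM.

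Of 18 type 1 program genes in CD4 cells 17 rose and 1 fell, led by the IL-18 receptor chain Il18rap (16.0 to 791 ± 72.5 CPM) and Il12rb2 (log2 fold change 4.81 ± 0.19). Of 17 cytotoxicity genes 13 rose and 2 fell, with the protease inhibitor Serpinb9 at 4.43 ± 0.30. Of 18 chemokine receptor and homing genes 12 rose and 3 fell (14 and 3 when adjusted over the list alone), Ccr2 among those that rose, and of 18 naive and quiescence genes 14 fell and 1 rose (15 and 1 when adjusted over the list alone). The set tests of these 4 lists kept an adjusted p under 0.05 with an estimated correlation (0.0021, 0.00193, 0.0341 and 0.0493). With the column number as a block, the homing and naive lists gave 0.0591 and 0.0894, and with only the 2 groups in the blocked fit the 4 lists gave 0.2725, 0.284, 0.284 and 0.36. Cell cycle genes rose in 29 of 30 members (adjusted p = 0.0671 with an estimated correlation), with Aurkb at 3.92 ± 0.23. Inhibitory receptor genes rose in 11 of 16 and fell in 1 (12 and 1 when adjusted over the list alone; adjusted p = 0.0533 with an estimated correlation), Tigit from 3.43 to 135 CPM and Ctla4 from 33.8 ± 5.74 to 221 ± 21.03 CPM. Glycolysis genes rose in 12 of 17 (13 rose and 1 fell when adjusted over the list alone; 0.0533 with an estimated correlation), and 12 of 21 costimulation and activation genes rose and 2 fell (13 and 3 when adjusted over the list alone; 0.0671). Il21, a cytokine of helper cells, rose by 5.83 ± 0.37, and the transcription factor Bhlhe40 by 4.59 ± 0.21.

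Of 17 type 2 program genes in CD4 cells 7 rose and 4 fell. The same counts were 7 and 8 of 18 for the type 17 program, 5 and 3 of 11 for NK receptors, 2 and 6 of 9 for iNKT identity and TCR segments, and 5 and 6 of 15 for immediate early genes. For regulatory T cell genes 2 rose and 4 fell of 10, with Foxp3 at 24.1 ± 8.80 CPM on day 0 and 10.4 ± 0.87 CPM on day 7 (adjusted p = 0.0295), and for follicular helper genes 4 and 1 of 9. For the interferon response 9 rose and 1 fell of 24, for oxidative phosphorylation 6 and 0 of 23, for cholesterol synthesis 2 and 9 of 18, for the unfolded protein response 2 and 3 of 13, for chromatin and lineage transcription factors 5 and 5 of 16, and for gamma delta T cell markers 1 and 1 of 6. Markers of other cells fell beside the naive genes: 11 of 13 B cell, 12 of 16 myeloid (2 rose), 10 of 11 erythroid and platelet, 5 of 8 thymocyte and 1 of 4 stromal and epithelial markers. The B cell list kept adjusted p = 0.00193 with an estimated correlation (0.00907 with the column number as a block and 0.2725 with only the 2 groups in the blocked fit), and the myeloid, erythroid and thymocyte lists gave 0.0923, 0.0671 and 0.0923. Of the 3 co-receptor genes, Cd8a and Cd8b1 fell (log2 fold changes −1.99 ± 0.58 and −1.23 ± 0.25). Cd4 at 750 ± 290 and 1069 ± 111 CPM did not pass. With the column number as a block and detected genes as a covariate, Cd4 passed (log2 fold change 0.96, adjusted p = 0.000195). In that fit Foxp3 no longer passed (adjusted p = 0.212). Adjusted over the list alone, 9 type 17 and 8 immediate early genes fell, 7 NK receptors rose, 3 regulatory T cell genes rose and 5 fell, 12 B cell and 11 erythroid genes fell, and the other counts of this paragraph were as given. In total 5349 of 15031 genes passed, 2612 higher and 2737 lower on day 7, and 47.2% of tested genes had groups that did not overlap, where chance gives 10% for 3 against 3. CD4 day 0 library 3 stood apart from the other day 0 libraries (Spearman 0.952 and 0.949, against 0.993 between the other 2), with Hba-a1 at 4300 CPM and Foxp3 at 13.9 CPM. Without it 6164 genes passed.

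CD8 cells of untreated hosts at day 7 likewise carried more effector, inhibitory receptor and proliferation transcripts than on day 0. Gzmb rose from 3.38 ± 1.06 to 2831 ± 660 CPM (n = 3 each; log2 fold change 9.71 ± 0.28, adjusted p = 1.79e-12), Tbx21 from 38.1 to 525 ± 26.2 CPM, Ifng from 10.3 to 65.5 ± 9.13 CPM and the activating receptor Klrk1 from 6.54 to 631 CPM. Pdcd1 rose from 3.68 to 951 ± 109 CPM (8.01 ± 0.22), Tigit from 0.581 to 106 ± 6.07 CPM and Havcr2 from 16.3 to 319 ± 37.7 CPM. Ccr7 fell from 1351 to 24.1 CPM. Cd8a fell from 950 ± 20.7 to 380 ± 27.1 CPM (−1.32 ± 0.11) and Cd8b1 by −0.78 ± 0.08. Among the B cell and myeloid genes that fell were Cd79a (135 ± 76.3 to 0.26 CPM) and Csf1r (419 ± 156 to 2.64 CPM).

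Of 16 inhibitory receptor genes in CD8 cells 12 rose and 3 fell, of 17 cytotoxicity genes 13 rose and 2 fell, and of 17 glycolysis genes 15 rose and 0 fell, with adjusted p = 0.0131, 0.0131 and 0.0317 with an estimated correlation. Of 18 type 1 program genes 17 rose (adjusted p = 0.0594 with an estimated correlation), all 30 cell cycle genes rose (0.131), and 22 of 23 oxidative phosphorylation genes rose (0.356). Of 18 naive and quiescence genes 17 fell, including Foxo1 (386 ± 21.3 to 109 ± 10.4 CPM; adjusted p = 0.13 for the list with an estimated correlation). Immediate early genes of T cell receptor signalling fell in 14 of 15 members (adjusted p = 0.162 with an estimated correlation), with Egr1 at 170 ± 34.1 on day 0 and 20.4 ± 0.145 CPM on day 7; Myc fell from 272 ± 8.15 to 61.5 ± 2.46 CPM. NK receptors rose in 8 and fell in 2 of 11, chemokine receptor and homing genes in 8 and 7 of 18, type 2 program genes in 8 and 5 of 13, type 17 program genes in 5 and 7 of 16, and cholesterol synthesis genes in 9 and 4 of 18. The same counts were 3 and 1 of 8 for iNKT identity, 8 and 5 of 19 for costimulation, 3 and 3 of 9 for regulatory T cells, 4 and 4 of 8 for follicular helper genes, 8 and 2 of 24 for the interferon response, 4 and 5 of 13 for the unfolded protein response, 4 and 7 of 16 for lineage transcription factors and 2 and 0 of 6 for gamma delta T cell markers. All 13 B cell, 12 of 16 myeloid, 8 of 11 erythroid, 6 of 9 thymocyte, all 3 co-receptor and 4 of 5 stromal and epithelial genes fell, while 3 myeloid and 1 stromal gene rose. Of these lists the thymocyte one kept adjusted p = 0.0317 with an estimated correlation. Adjusted over the list alone, 1 interferon response gene fell, 4 regulatory T cell, 5 unfolded protein response and 4 myeloid genes rose, 7 thymocyte genes fell, and the other counts were as given. The test called 8847 of 14586 genes, 4506 higher and 4341 lower on day 7, and 67.1% of tested genes had groups that did not overlap, where chance gives 10%. The count exceeded 1.5 times its main value, or fell below it by that factor, under none of the alternatives run for either cell type.

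**Figure D4:**
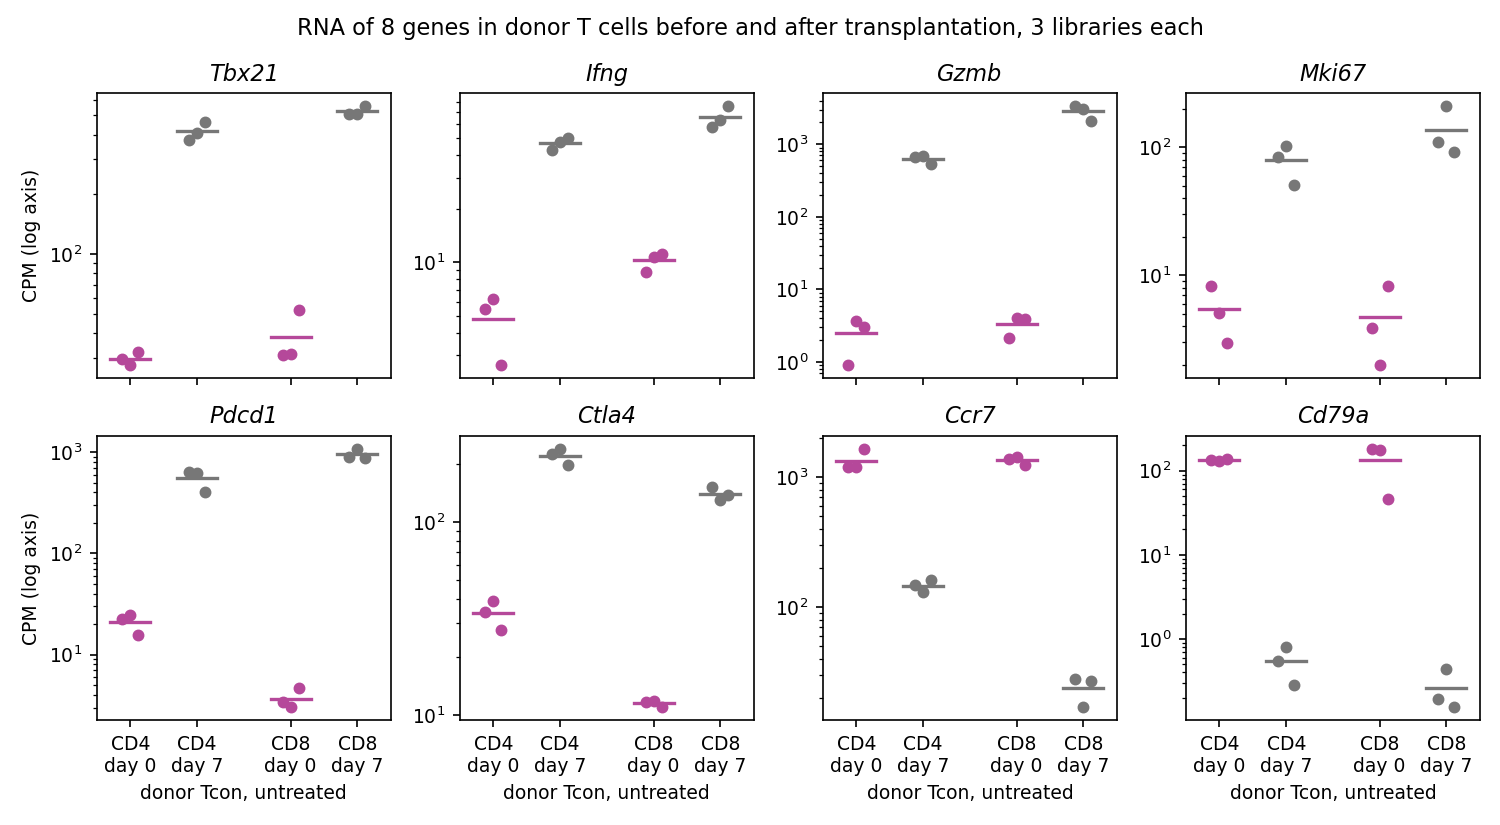
CPM of 8 genes (log axis) in donor CD4 and CD8 cells on day 0 and in untreated hosts on day 7, with 1 point per library (3 per group) and a line at the mean. Tbx21, Ifng, Gzmb, Mki67, Pdcd1 and Ctla4 lay higher, and Ccr7 and Cd79a lower, on day 7 in both cell types.

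The transfer comparisons asked whether giving iNKT1, iNKT2 or iNKT17 cells changed donor T cells at day 7. Among the named CD8 genes, 5 passed with every treatment, and these calls depended on single libraries. Without untreated library 1 only Ctla4 with iNKT2 and iNKT17 kept its call. Abcg3 with iNKT1 or iNKT2 and Ctla4 with iNKT1 lost theirs whichever compared library was left out. Cirbp, which encodes a cold-inducible RNA-binding protein, fell from 154 ± 19.3 CPM in untreated to 60.6 ± 11.9, 64.9 ± 8.26 and 74.8 ± 15.5 CPM with iNKT1, iNKT2 and iNKT17 (n = 3 each; log2 fold changes −1.34 ± 0.17, −1.24 ± 0.17 and −1.04 ± 0.17; adjusted p = 0.0137, 0.0167 and 0.0216). The inhibitory receptor Ctla4 fell from 140 ± 11.3 to 87.1 ± 11.7, 70.1 ± 7.08 and 67.9 ± 7.11 CPM (−0.69 ± 0.12, −1.001 ± 0.12 and −1.05 ± 0.12; adjusted p = 0.0375, 0.00562 and 0.00318). The splicing factor Srsf7 rose from 46.3 ± 1.02 to 103 ± 3.81, 95.3 ± 21.5 and 95.3 ± 20.6 CPM, the heat shock protein Hsph1 from 99.7 ± 15.8 to 171 ± 13.4, 170 ± 9.29 and 163 ± 13.3 CPM, and Abcg3 from 4.16 ± 0.459 to 8.68 ± 0.795, 8.89 ± 0.993 and 8.96 ± 2.22 CPM.

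**Figure D5:**
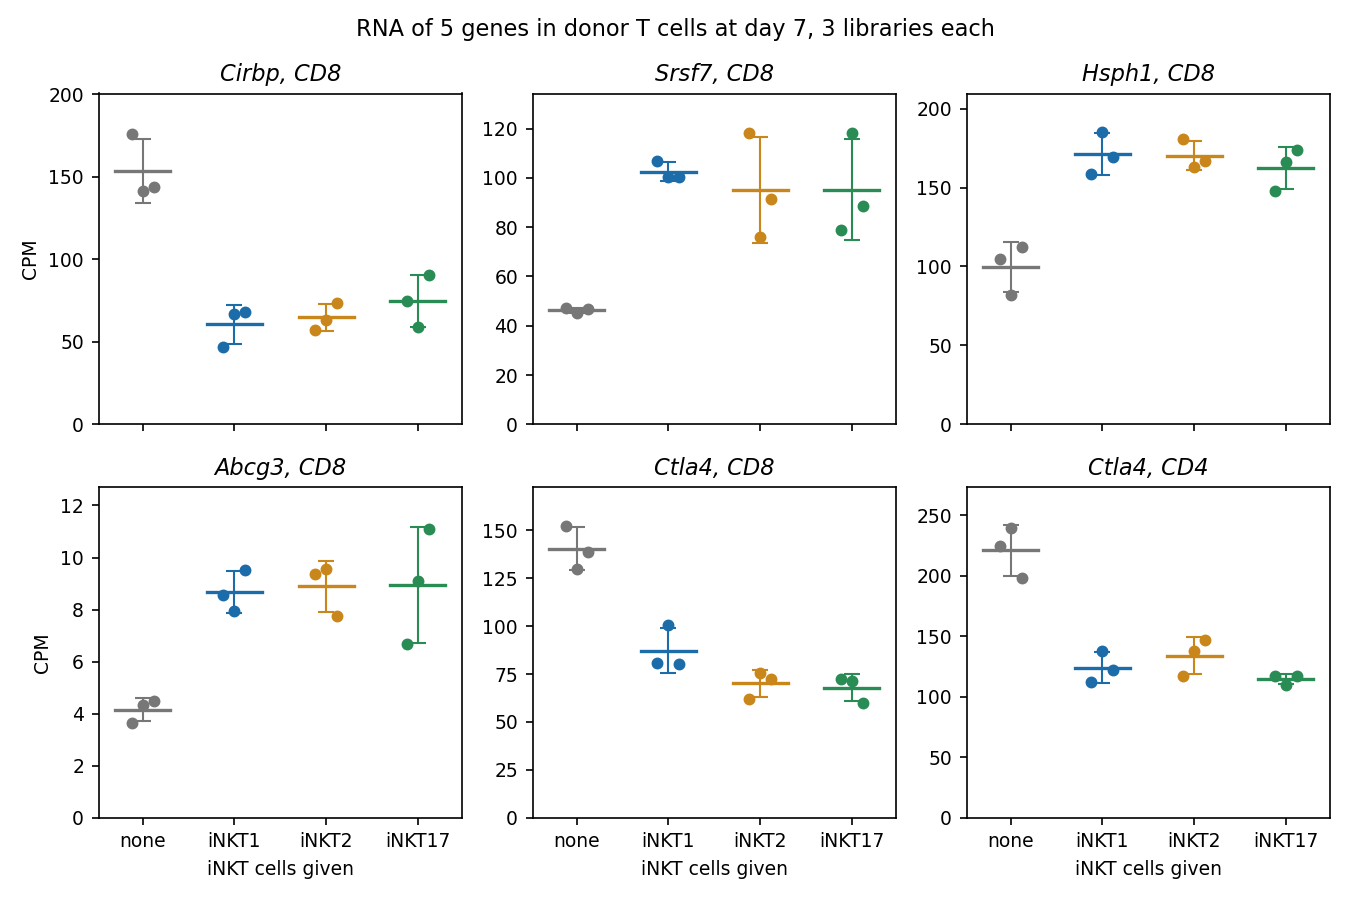
CPM (axis from 0) of Cirbp, Srsf7, Hsph1, Abcg3 and Ctla4 in CD8 cells and of Ctla4 in CD4 cells at day 7 with no iNKT cells or with iNKT1, iNKT2 or iNKT17 cells; points are libraries (3 per group), lines means and bars SD. In CD8 cells Cirbp and Ctla4 lay lower, and Srsf7, Hsph1 and Abcg3 higher, in each treated group than in untreated. Ctla4 in CD4 cells did not pass in the main fit.

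With iNKT1 cells 23 of 14586 CD8 genes passed, 13 higher and 10 lower. Gpr15, a homing receptor, rose from 0.538 ± 0.0417 to 2.03 ± 0.769 CPM (log2 fold change 1.91 ± 0.34, adjusted p = 0.0408), and Rprd2 fell from 32.9 ± 2.70 to 16.4 ± 3.45 CPM. With iNKT2 cells 16 passed, 13 higher and 3 lower. Myc, a driver of growth and metabolism, rose from 61.5 ± 2.46 to 94.98 ± 11.9 CPM (0.63 ± 0.10, adjusted p = 0.0393) and the cyclin gene Ccnd2 by 0.88. In this comparison same-numbered libraries deviated together. With the column number as a block and only the 2 groups in the fit 420 genes passed, 202 higher and 218 lower. With the block and all day 7 libraries 5 passed, and Srsf7, Hsph1, Abcg3 and Myc each gave adjusted p = 0.067; Cirbp and Ctla4 passed in both blocked fits. With iNKT17 cells 30 passed, 20 higher and 10 lower. Myc rose to 90.9 ± 11.4 CPM (adjusted p = 0.0424), and the IL-18 receptor Il18r1 fell from 153 ± 15.9 to 84.4 ± 13.2 CPM (−0.86 ± 0.16, adjusted p = 0.0424).

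Gzmb and Ifng did not pass in CD8 cells in any treatment. The log2 fold changes of Gzmb were −0.05, −0.08 and −0.15 (SE 0.19 each) and those of Ifng 0.13, 0.37 and −0.03 (SE 0.23 each) for iNKT1, iNKT2 and iNKT17. Pdcd1 gave −0.39, −0.67 and −0.62 (adjusted p = 0.328, 0.105 and 0.101). In the inhibitory receptor list 1 of 16 genes fell per treatment, Ctla4 itself, and 2, 3 and 4 when adjusted over the list alone (adjusted p = 0.245, 0.378 and 0.238 with an estimated correlation). None of 24 interferon response genes passed, and 0, 8 and 1 rose when adjusted over the list alone (adjusted p = 0.8, 0.529 and 0.562 with an estimated correlation). None of 13 unfolded protein response genes passed, and 0, 4 and 5 rose when adjusted over the list alone (0.8, 0.378 and 0.508 with an estimated correlation). Of 17 cytotoxicity genes 0 passed and 2, 1 and 2 rose when adjusted over the list alone. The blocked fit of iNKT2 and untreated alone differed: Pdcd1 passed (adjusted p = 0.0107), 1 inhibitory receptor gene rose and 3 fell, 5 of 24 interferon response and 4 of 12 unfolded protein response genes rose, and 2 cytotoxicity genes rose and 1 fell (adjusted p = 0.528 for each list with an estimated correlation). In that fit the immediate early, B cell, myeloid and erythroid lists were also called upward with the preset correlation (adjusted p = 0.00342, 0.0154, 0.0466 and 0.038), again with 0.528 each when it was estimated.

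These CD8 counts depended on single libraries and on the model. Leaving out untreated library 1, 2 or 3 gave 0, 6 and 9 calls for iNKT1, 2, 6 and 35 for iNKT2, and 1, 7 and 49 for iNKT17; leaving out treated library 1, 2 or 3 gave 0, 2 and 3, then 0, 12 and 4, then 16, 2 and 7. DESeq2 called 385, 353 and 483 genes, and with only the day 7 libraries in the fit edgeR called 14, 2 and 17. With only the 2 compared groups in the fit it called 3, 2 and 6.

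In CD4 cells the main edgeR fit called 0 genes for iNKT1, iNKT2 or iNKT17 against untreated, with 1008, 1204 and 1170 of 15031 genes at an unadjusted p under 0.05, while DESeq2 called 123, 116 and 213. Some other edgeR settings without a block gave calls for iNKT1 or iNKT17, as listed with the alternatives below. For iNKT17, same-numbered libraries deviated together with those of untreated, though the titles of the 2 groups do not carry the same numerals. The column number as a block gave 11 calls in the fit of all CD4 libraries. With only the 2 groups in the fit it gave 461 (217 higher, 244 lower). Ctla4 measured 221 ± 21.03 CPM in untreated and 124 ± 12.9, 134 ± 15.4 and 115 ± 4.25 CPM with iNKT1, iNKT2 and iNKT17 (n = 3 each; log2 fold changes −0.83, −0.72 and −0.94, SE 0.15 each; adjusted p = 0.228, 0.283 and 0.0646). The inhibitory receptor Lag3 gave −1.03, −1.08 and −1.42 and did not pass. In the 2 blocked fits of iNKT17 Ctla4 passed (adjusted p = 0.0394 and 0.00835), and Lag3 passed in the fit of the 2 groups alone (0.0135). The genes named in CD8 had CD4 log2 fold changes of −1.48, −0.98 and −0.90 for Cirbp (SE 0.23 each), 0.88, 1.0 and 0.94 for Srsf7, 0.60, 0.70 and 0.39 for Hsph1, and 1.07, 1.25 and 1.37 for Abcg3, with adjusted p of 0.114 or more in the main fit. Among inhibitory receptor genes 0 of 16 passed, and 3, 5 and 8 fell and 0, 0 and 1 rose when adjusted over the list alone (adjusted p = 0.158, 0.231 and 0.0665 with an estimated correlation). Of 24 interferon response genes 0 passed, and 1, 7 and 0 rose when adjusted over the list alone (0.767, 0.231 and 0.301 with an estimated correlation). In the blocked fits of iNKT17, with all CD4 libraries and with the 2 groups alone, 2 and 7 inhibitory receptor genes fell (0.113 and 0.513 with an estimated correlation) and 0 and 4 interferon response genes rose (0.116 and 0.772). Without a block, the type 17 list with iNKT1 was the only treated list to keep a set test call with an estimated correlation (adjusted p = 0.0393, downward), though 0 of its 18 members passed; Ltb4r1 gave −0.56 ± 0.19 and Ccr6 −1.48 ± 0.74. The myeloid gene Lyz2 measured 47.6 ± 18.5 CPM in untreated and 170 ± 81.0, 118 ± 58.7 and 86.7 ± 40.9 CPM with iNKT1, iNKT2 and iNKT17, and 13, 12 and 13 of 16 myeloid genes had positive fold changes (medians 0.86, 0.74 and 0.66). None of the 16 passed; 2, 0 and 0 rose and 0, 2 and 0 fell when adjusted over the list alone. The set test of this list gave adjusted p = 8.19e-05, 0.0245 and 0.0552 upward with the preset and 0.198, 0.492 and 0.587 with an estimated correlation. For iNKT17 the 2 blocked fits gave 0.0256 and 0.02 with the preset and 0.569 and 0.772 with an estimated correlation for the myeloid list, and 0.042 and 0.031 with the preset, against 0.0741 without a block, for the immediate early list. Groups did not overlap for 19.8%, 14.4% and 16.6% of tested CD4 genes, where chance gives 10% on average. Genes are not independent, so single comparisons can lie well off that value. Between treatments (iNKT2 and iNKT17 against iNKT1, iNKT17 against iNKT2) the shares were 11.9%, 9.53% and 4.66% in CD4. In CD8 they were 18.7%, 14.7% and 7.45%, with 0 calls in each. The CD4 shares against untreated therefore do not show an effect by themselves.

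Whether an iNKT effect differed between CD8 and CD4 cells was tested as an interaction over 15601 genes. Each of the 3 treatments gave 0 calls with edgeR (377, 321 and 538 genes at an unadjusted p under 0.05), and DESeq2 gave 3, 7 and 3. The smallest adjusted p was 0.816, for iNKT17. The CD8 effects of Cirbp and Ctla4 were therefore not shown to differ from those in CD4. No list member passed over all genes, and no list passed with an estimated correlation. With its preset correlation camera passed the cell cycle list upward for iNKT1, iNKT2 and iNKT17 (29, 30 and 30 of 30 tested genes positive; adjusted p = 1.06e-04, 5.5e-09 and 2.68e-12, against 0.815, 0.357 and 0.334 with an estimated correlation). Myeloid markers passed downward for iNKT1 and iNKT17 (3 of 16 positive in each; 4.06e-06 and 0.00347, against 0.442 and 0.4). The type 1 program passed upward for iNKT2 and iNKT17 (0.00118 and 0.00693, against adjusted p = 0.282 and 0.4), type 17 and gamma delta lists for iNKT2 (0.0351 and 0.013, against 0.294 and 0.282), and inhibitory receptor and glycolysis lists for iNKT17 (0.00352 each, against 0.334). Across genes, which are not independent replicates, the CD8 and CD4 fold changes had Pearson correlations of 0.171, 0.212 and 0.171 and Spearman correlations of 0.365, 0.448 and 0.338 for iNKT1, iNKT2 and iNKT17. Titles list each day 7 CD4 library with a CD8 library of the same experiment and numeral, and the main interaction fit held no such pairing. Whether the 2 libraries shared an animal is not stated. Shared samples could raise these correlations, so they do not by themselves show a shared effect of treatment.

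The treatments were also set against each other. In CD8 cells edgeR called 0 genes for iNKT2 against iNKT1, iNKT17 against iNKT1 and iNKT17 against iNKT2 (1731, 1355 and 534 at an unadjusted p under 0.05; DESeq2 35, 11 and 1). For iNKT17 against iNKT1, whose same-numbered libraries deviated together, the block also gave 0 calls, while the preset set test then called the immediate early list upward and the gamma delta T cell list downward (adjusted p = 0.0019 and 0.00493 with all day 7 libraries, 0.00915 each with the 2 groups alone) and, in the latter fit, the cell cycle list upward (0.0111). With an estimated correlation the first 2 lists gave 0.378 each with all day 7 libraries, and the 3 lists gave 0.972 each with the 2 groups alone. Bcl6, a repressor that guides follicular helper cells, measured 2.97 ± 1.08 CPM with iNKT1 and 0.841 ± 0.115 with iNKT2 (log2 fold change −1.81 ± 0.27, adjusted p = 0.115), and Myc gave 0.56 ± 0.10 (adjusted p = 0.202). In CD4 cells edgeR also called 0 (513, 334 and 277 at an unadjusted p under 0.05; DESeq2 4, 6 and 2), with Izumo1r, a folate receptor family gene, at 0.85 ± 0.22 for iNKT2 against iNKT1 (adjusted p = 0.872). Without iNKT1 library 1, 1 gene was called in CD8 for iNKT2 against iNKT1.

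The treatments share their untreated libraries, so correlations and covariances between them exceed 0 with no effect. Between pairs of CD8 treatments (iNKT1 with iNKT2, iNKT1 with iNKT17, iNKT2 with iNKT17) fold changes correlated at 0.479, 0.511 and 0.59, and unchanged simulated groups against the same libraries gave means of 0.5, 0.507 and 0.507. The covariances were 0.201, 0.212 and 0.254, against 0.113, 0.114 and 0.115 simulated, differences of 0.088, 0.0974 and 0.139. The simulations held no pairing of libraries by number, so these differences do not account for it. Pairs shared 5, 4 and 7 raised and 2, 6 and 3 lowered genes. Independent lists would share 0.0116, 0.0178 and 0.0178 raised and 0.00206, 0.00686 and 0.00206 lowered, and no simulation shared any. Neither value can decide whether the overlap exceeds that from shared controls. Independence ignores the shared untreated libraries, and unchanged simulated groups have no true calls to share. In CD4 the correlations were 0.506, 0.584 and 0.598, against 0.495, 0.501 and 0.508 simulated, with covariance differences of 0.0845, 0.114 and 0.133. The 3 untreated libraries were not split between treatments, and part of each excess may come from the shared libraries.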

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

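For the patterns weighed here, the tests of library depth, of other cells in the day 0 libraries and of other splits of the libraries were chosen only after the result was seen, as was the column number as a block, and the detected-genes covariate was added after seeing the data, before its result for Cirbp was known.

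Of all UMIs, 26.51% in thymus A and 24.06% in thymus B lay outside the kept cells. They stand here as signal in barcodes that no comparison uses, and no explanation was tested.

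In CD8 cells Cirbp was lower, and Hsph1 and Srsf7 higher, with each of the 3 iNKT treatments than in untreated. The number of detected genes as a whole cause is argued against: with it as a covariate Cirbp kept an adjusted p under 0.05 in 3 of 3 comparisons (log2 fold changes −1.39, −1.32 and −1.12; adjusted p = 0.00366, 0.0148 and 0.0287). With the column number as a block in the same fit of day 7 libraries the fold changes were −1.38, −1.28 and −1.08 (−1.36, −1.26 and −1.06 with the block alone), and Cirbp passed with iNKT1 only (adjusted p = 0.0378, 0.0748 and 0.0895, against 0.0287, 0.0431 and 0.0416 with the block alone). A heat-shock response in the treated libraries could not be decided: the median log2 fold change of 14 tested heat-shock genes (Hsph1 left out) was 0.2447, 0.09483 and 0.1183 for iNKT1, iNKT2 and iNKT17, with camera p = 0.0314, 0.0216 and 0.142 with the preset and 0.134, 0.112 and 0.292 with an estimated correlation, and no member passed in CD8. In CD4, where Cirbp, Hsph1 and Srsf7 were not called, the medians were 0.15, 0.22 and 0.12 with camera p = 0.0094, 0.000522 and 0.115 with the preset and 0.0201, 0.00419 and 0.125 with an estimated correlation, upward each time, and again no member passed. Rbm3, a cold-inducible gene like Cirbp, gave −0.32, −0.47 and −0.52 in CD8 and −0.49, −0.45 and −0.58 in CD4, and was called in neither. An effect of the iNKT cells stays open beside a difference in handling, which no label records.

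B cell, myeloid and erythroid transcripts were higher on day 0 than on day 7. Library depth is argued against, since the ratio of mean total counts, day 0 over untreated day 7, was 1.024 in the cell type where it was higher. Cells of other types in the day 0 libraries and a fall within T cells after transplantation cannot be told apart. That 84.62% of 13 tested B cell markers fell in CD4 and all 13 in CD8 restates the pattern and decides nothing. Abundant genes of B and myeloid cells stood at 4885 ± 2931 and 2483 ± 1075 CPM (Cd74) and 1346 ± 628 and 743 ± 229 CPM (H2-Aa) on day 0 in CD4 and CD8, against 51.3 and 26.9, and 6.14 and 6.18 CPM on day 7. A sort on CD4 or CD8 and a T cell marker would remove such cells, and the labels give no gate for these libraries. Both stay open because day and any other cells change together.

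ATAC libraries with the same replicate number deviated together. A deviation confined to background counts in low-signal regions is argued against. The lowest correlation between groups in the 5452 regions with the highest mean CPM was 0.8167. A difference in background over a whole library would reach strong regions too, so this value cannot decide it. Regions over 10 kb held more of the counts in library 1 than in library 2 of iNKT1 (2.56% and 1.52%), iNKT2 (7.09% and 1.85%) and iNKT17 (5.34% and 1.53%). Library depth is argued against by the pair iNKT1 and iNKT17, whose replicates have opposite depth order and still correlated at 0.502. A shared day or batch was not tested because no label gives one, and no biological explanation was tested.

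Other splits of the 6 libraries gave the following counts of calls; 10 splits are too few for a share under 0.05. Day 7 untreated against day 0 gave 5349 calls in CD4 and 8847 in CD8, with 0 in the highest other split, so 1 split of 10 was as large in each. In CD8 the real counts were 23 for iNKT1 (highest other 0; 1 of 10 as large), 16 for iNKT2 (highest other 1; 1 of 10) and 30 for iNKT17 (highest other 52; 2 of 10). The split with 52 calls set untreated library 1 with iNKT17 libraries 2 and 3 against the rest, which points to a structure of these samples beside the treatment. For CD8 iNKT2 and CD4 day 7 untreated against day 0, taken as paired by number, 3 of the other 9 splits part as many pairs as the real one and 6 part fewer, and none of the 9 had over 1 call. In the 9 comparisons of CD4 or CD8 treated libraries with 0 calls (3 of CD4 treatments against untreated, 3 between CD4 treatments and 3 between CD8 treatments), all 10 splits were as large, which a real count of 0 fixes, so they decide nothing; the highest other count was 2 for CD4 iNKT17 against iNKT2, 1 for CD8 iNKT17 against iNKT1 and against iNKT2, and 0 for the rest. For the difference between CD8 and CD4 effects, with 0 calls, 25 of 25 splits were as large for each treatment, which the count of 0 again fixes, with highest other counts of 0, 2 and 2.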

How the results depend on the processing

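Of the alternatives here, tests with the number of detected genes as a covariate, with column numbers of donor T cells as a block, without CD4 day 0 library 3, without ATAC regions over 10 kb and with resolution 0.4 for bulk against clusters were chosen only after the result was seen. Where a value changed, the cause was not tested. In iNKT RNA 0% of simulated changes of 1 log2 unit were called, all placed in genes with a mean log2 CPM of at least 4. This limits what the 2 libraries per group show. In the simulated iNKT RNA and ATAC data, false calls also took a larger share of calls than the adjusted p threshold allows. No named gene that was called in the main or the alternative fit reversed its direction. Sign changes of genes called in neither fit were not counted. Of the single-gene values other than leave-one-out, 18613 kept their side of the threshold, 411 newly passed and 226 no longer passed. Of the leave-one-out values 14710, 88 and 239 did so. Counts for day 7 against day 0 stayed within 1.5 times their value (CD4 4106 to 7483, CD8 6357 to 8856). The test of RNA against ATAC direction passed under both of its alternatives in each of the 3 comparisons.

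For iNKT2 against iNKT1, iNKT17 against iNKT1 and iNKT17 against iNKT2 RNA, DESeq2 called 1177, 1820 and 1472 genes, and edgeR without a filter 445, 559 and 339. With only the compared groups iNKT17 against iNKT2 gave 43. Leaving out single libraries gave 153 to 315, 195 to 1040 and 157 to 831.

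The replicate block gave 158, 228 and 84 RNA calls in this order. Same-numbered RNA libraries did not deviate together (correlations −0.0548, 0.0561 and −0.0338 in the same order), so they share only a number. In ATAC, with its pairing, the block gave 29150, 29131 and 10102 regions and moved no other count of these sublineages by over 1.5 times. For donor T cells the column numbers were used as a block. Same-numbered libraries had r over 0.1 in 17 of 30 CD4 pairs, 10 of 18 day 7 CD8 pairs and 9 of 12 pairs of CD4 with CD8 (lowest −0.61, −0.559 and −0.237), and 9 of 15, 4 of 12 and 19 of 24 libraries were closest to their own number, a hint from the data. Only 4 comparisons had all 3 pairs over 0.1. With the block, in the fit of all CD4 or all day 7 CD8 libraries, iNKT1, iNKT2 and iNKT17 against untreated gave 2, 4 and 11 calls in CD4 and 3, 5 and 34 in CD8. With only the compared groups the block gave 5, 1 and 461 in CD4 and 7, 420 and 0 in CD8, and with detected genes in the shared blocked fit 26, 52 and 183 in CD4 and 7, 4 and 4 in CD8. Of the comparisons taken as paired, it left CD4 day 7 against day 0 within 1.5 times (5720 and, with only the compared groups, 4320 calls) and CD8 iNKT17 against iNKT1 at 0. The other comparisons between treatments stayed at 0, as did the difference between CD8 and CD4 effects with CD4 and CD8 columns of one number as the block. In the blocked day 7 fit of CD8 iNKT2, the preset set test newly called the 4 lists that it called with the 2 groups alone, and the type 1, follicular helper and thymocyte lists (adjusted p = 0.0456, 0.0456 and 0.0474), each over 0.05 with an estimated correlation. In CD4 day 7 against day 0 with only the compared groups it no longer called cholesterol synthesis (0.0716). Beyond these and the changes given beside their results, the block changed no other set test call of the paired comparisons. No paired analysis was run for CD8 day 7 against day 0, since the CD8 day 0 columns carry no numbers of their own and their order was not used for pairing. The experiment term and blocks by title, and alternatives with CD4-positive or CD4-negative iNKT1 libraries, were not run.

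For CD4 with iNKT1, iNKT2 and iNKT17 against untreated (0 calls each), DESeq2 called 123, 116 and 213. RLE factors gave 4, no filter 1 and only day 7 libraries 2 for iNKT17, and only the compared groups 3 for iNKT1. The detected-genes covariate gave 13 and 51 for iNKT1 and iNKT17, and 25 and 80 with only day 7 libraries. Without CD4 day 0 library 3 iNKT17 gave 5 and the others 0. Leaving out single compared libraries gave 0 calls throughout.

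For CD8 in the same order, DESeq2 called 385, 353 and 483, only the compared groups gave 3, 2 and 6, only day 7 libraries 14, 2 and 17, the covariate 172, 4 and 17, and both together 57, 3 and 9. No filter gave 57 for iNKT17. Leaving out single libraries gave 0 to 9, 0 to 35 and 1 to 49. Between treatments (iNKT2 and iNKT17 against iNKT1, iNKT17 against iNKT2) DESeq2 called 4, 6 and 2 in CD4 and 35, 11 and 1 in CD8. In CD8 the compared groups alone gave 4 and 2 for the first and last, no filter 1 for the last, and leaving out single libraries 0 to 1 for the first. For the difference between CD8 and CD4 effects DESeq2 called 3, 7 and 3.

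Leaving out single ATAC libraries gave 11572 to 17855, 12884 to 17368 and 1572 to 4985 regions. DESeq2 called 23451, 23391 and 6718, and without the 35 regions over 10 kb 22126, 21895 and 4798 passed. The iNKT2-like share was 49.28% and 54.48% at resolution 0.4 against 0 otherwise, and iNKT1-like shares ran from 31.4% to 42.5% in thymus A and 22.8% to 29.0% in thymus B. At resolution 0.8 comparisons with iNKT2-like clusters gave no value, since none was named. Over all genes, bulk against clusters gave 0.2595 and 0.2669. Of 576 gene list tests, camera called 123 with the preset correlation, 10 with an estimated correlation and 94 were called by fry.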

Other observations

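In this part the tests with the column number as a block were chosen only after the result was seen, and which genes and lists to mention was decided with their values in view.

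Genes of gamma delta T cells were measured in all 3 iNKT sublineages. The receptor constant gene Tcrg-C1 stood at 138 ± 3.77, 255 ± 40.0 and 588 ± 136 CPM in iNKT1, iNKT2 and iNKT17 libraries (n = 2 each) and rose in iNKT17 over iNKT1 (log2 fold change 2.09 ± 0.29, adjusted p = 0.00502). Tcrg-C4 rose in iNKT2 and in iNKT17 over iNKT1 (1.56 ± 0.29 and 1.66 ± 0.29, adjusted p = 0.0339 and 0.0173). In all, 1 of 6 tested markers rose in iNKT2 against iNKT1 and 2 in iNKT17 against iNKT1 (adjusted p = 0.397 and 0.195 with an estimated correlation), and 0 in iNKT17 against iNKT2. Trdc, the delta chain gene, stood at 0.524, 1.47 and 0 CPM. Cd163l1 measured 26.0, 8.56 and 424 CPM and did not pass. The peptidase gene Dpp4 measured 0.0327 CPM in iNKT1 and 194 ± 46.0 in iNKT2, Igfbp4 0.0313 and 99.1 ± 1.91, and the noncoding transcript AW112010 fell from 156 ± 40.6 in iNKT2 to 0.21 ± 0.251 CPM in iNKT17 (log2 fold change −9.57 ± 0.83).

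Of 130 ATAC regions at chromatin and lineage transcription factor genes, 39 rose and 31 fell in iNKT2 against iNKT1, 48 and 20 in iNKT17 against iNKT1, and 10 and 3 in iNKT17 against iNKT2. Of 67 regions at immediate early genes 3 rose and 17 fell in iNKT2, and 2 and 22 in iNKT17, against iNKT1. Of 51 regions at cytotoxicity genes 25 and 24 fell and 1 and 4 rose. With an estimated correlation adjusted p was 0.962, 0.654 and 0.929 for the transcription factor, 0.346 and 0.336 for the immediate early and 0.346 and 0.336 for the cytotoxicity list. In treated CD8 cells, Gzma measured 83.4 ± 38.5 CPM in untreated and 206 ± 149, 290 ± 126 and 406 ± 306 CPM with iNKT1, iNKT2 and iNKT17, Klrg1 34.2, 75.3, 76.4 and 87.5, and Gzmm 8.94, 16.6, 20.4 and 20.8 CPM. None of these 3 genes was called in the main fit (adjusted p of 0.0667 or more for Gzmm). With the column number as a block in the fit of day 7 libraries, Klrg1 passed with iNKT1, iNKT2 and iNKT17 (adjusted p = 0.0118, 0.0168 and 0.0024), and Gzma and Gzmm with iNKT17 only (0.045 each). With the block and only untreated and 1 treatment in the fit, Gzma, Klrg1 and Gzmm passed with iNKT2 (3.4e-05, 0.00205 and 0.021), Klrg1 alone with iNKT1 (0.0436) and none with iNKT17, so these calls depend on which libraries share the fit. In CD4 cells Prf1, the perforin gene, measured 168 ± 24.0, 94.9, 96.1 and 80.3 CPM, and the gut homing receptor Ccr9 60.5, 23.8, 28.0 and 21.4 CPM, with adjusted p of 0.103 or more in the main fit. With the block in the fit of all CD4 libraries neither passed. With the detected-genes covariate added there, Prf1 passed with iNKT17 (adjusted p = 0.0276) and Ccr9 with iNKT1 and iNKT17 (0.0495 and 0.0218), and with the block and only untreated and 1 treatment in the fit Prf1 passed with iNKT17 (0.00928) and Ccr9 with iNKT1 (0.0368).

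Over the 2 thymi the iNKT1-like share was 31.6 ± 10.6%, the iNKT17-like share 16.1 ± 6.43% and the interferon-responding share 25.5 ± 5.89% (mean ± SD). The last name is unstable. No cluster took it at resolution 0.4 or with thymus B clustered alone. With thymus A alone, the cluster of that name had 0 of its markers among its top 10 genes. The 35 ATAC regions over 10 kb, of which the widest spans 9706373 bp, held 1.52% to 7.09% of the counts of a library, with 2.56% and 1.52% in iNKT1, 7.09% and 1.85% in iNKT2 and 5.34% and 1.53% in iNKT17 libraries 1 and 2. All 35 cross a power of 10 in their coordinates. They may come from how the coordinates were put together and need not be open over their whole width, which was not tested.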
